A study of Arabidopsis thaliana with 6 samples.

How the data were processed

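RNA from whole cotyledons of wild-type Arabidopsis thaliana was measured on 6 arrays. Per the labels' protocols, seedlings grew for 6 days in liquid MS medium at 22 °C under continuous light. Cotyledons were then cultured with 2,4-D at 1.25 mg/L, kinetin at 0.25 mg/L, bikinin at 10 µM and 5% glucose or sucrose. Total RNA was amplified, labelled with biotin and hybridised, again per the labels. The amplification copies small amounts of RNA and can change the relative level of transcripts, and signal at the low end mixes transcript and background.

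The values used are the authors' deposited log2 signals per probe set, 1 column per array. Per the submitters' processing notes they were made with GCOS, with no version named; the background correction, the normalization and the log base are not given in the sources used here. The log base was inferred from the values: the largest, 14.2, is 19217 on a linear scale as log2, within the 65535 of a 16-bit scanner, and would be 1.5e+06 as a natural log. The deposited medians of the 6 arrays were 5.33 (glucose 0 h), 5.88 (glucose 24 h), 5.51 (glucose 48 h), 5.47 (sucrose 0 h), 5.92 (sucrose 24 h) and 5.88 (sucrose 48 h), so the arrays were not centred on a common median.

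The table held 38408 probe sets, of which 98 were control probe sets, left out of all tests, and 38310 were other probe sets. The platform's probe table listed 17481 of these: 16722 with 1 gene, 759 with several, from which no gene was named, and 20829 probe sets were not listed and stay unnamed here. Symbols were updated through the gene identifiers to the RefSeq gene table of assembly TAIR10.1, where 16574 of the 1-gene probe sets matched, at 16505 loci. A gene is given by symbol and locus tag, whose first digit is its chromosome, and no coordinates were used. A block of 7079 unlisted probe sets with consecutive odd identifiers had array medians from 3.62 to 5.22, further apart than those of the listed probe sets (5.37 to 5.54).

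Because the arrays' trimmed means (2% at each end, linear scale) ranged from 166.6 to 207.4, past a preset tolerance of 5%, each array was scaled to their mean. Signals were then raised to a floor at the 40th percentile of all arrays pooled (4.90 on the log2 scale), and probe sets above it on at least 2 arrays were tested: 25826, of which 10662 had 1 gene. A group whose arrays all lay at the floor has only a bound, written as at least so many fold against the floor. Named values stay relative to the scaling.

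Every sugar and time was a group of 1 array, so the spread came from the factorial design. The main model in limma 3.58.1 (R 4.3.3; lmFit, eBayes with an intensity trend, two-sided, Benjamini-Hochberg at 0.05) had 4 coefficients: 1 mean per time and 1 sucrose minus glucose term for the cultured arrays. Its 2 residual degrees of freedom came from the difference of the 0 h pair, taken as having no sugar effect, and from the change of the sugar difference between 24 and 48 h. The prior added 3.24 degrees of freedom. Time differences are means over both sugars, 2 arrays against 2. A second model of 5 coefficients kept the 4 cultured arrays apart, with 1 residual degree of freedom from the 0 h pair, and tested each time's sugar difference and its change. The labels do not say whether arrays came from separate cultures or days, so p-values measure only the spread between these arrays, which may be technical. Pairs of arrays were also compared by the number of probe sets at least 2-fold apart among those above the floor on at least 1 of them.

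There were 17 gene lists with 404 genes: xylem vessel, phloem, procambium and cambium, cell cycle, photosynthesis, anthocyanin, sugar starvation, sucrose and hexose metabolism and transport, starch, brassinosteroid synthesis, cytokinin response, auxin response, ABA and osmotic response, defence, epidermis, guard cell and reference genes. All were written before the data were examined, as were the models, thresholds, alternatives and the rule for named genes. Only 67 list genes had a named probe set and 59 were tested, so each list is a small sample of its genes: 3 of 38 xylem vessel, 4 of 34 phloem, 5 of 29 procambium and cambium, 3 of 33 cell cycle, 9 of 45 photosynthesis and 4 of 13 anthocyanin genes. The 11 lists with at least 3 tested genes entered camera with a preset correlation of 0.01, with the probe set of highest mean signal per gene, and an estimated correlation and fry as alternatives. For pairs of arrays, a list's median was placed among 10000 random lists of the same size matched on mean signal.

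Genes were named by a fixed rule: per comparison the 10 highest and 10 lowest differences past the threshold with 1 gene and a signal above the floor on every array compared, or, where none passed, the 5 with the largest difference of the same sign on both array pairs. The rule added up to 4 list members past the threshold, and the members of the xylem, phloem and procambium lists whether past it or not. Other list members named were chosen after their values were seen.

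The models were tested on simulated data with the real means and the fitted variance prior. With 200 of 25826 probe sets changed, the 24 h comparison recovered 0% of changes of 1 on the log2 scale, 24.1% of changes of 2 and 95.8% of changes of 4. With 10000 changed, these were 58.2%, 92.7% and 99.3%, with 2.94% false among the calls. For the common sugar term with 200 changed, 3.39%, 14.3% and 85.9% were recovered. Among 200 unshifted random sets, 3% had a camera p under 0.05. The simulated noise was independent between probe sets, so this share does not cover lists whose genes vary together. It was also alike on all arrays, drawn from the model's own prior and not raised to the floor. The recovered and false shares thus hold where the model's assumptions are met, and are not error rates of the real calls.

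Alternatives were quantile normalization, median centring, other floors and filters, other variance priors, each array left out in turn, and a sugar term over all 3 times. Signals as deposited, omission of the block of odd identifiers, gene families by symbol and the list tests of the change of the sugar difference were added after seeing the data. Figures were drawn with matplotlib 3.10.9.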

Results

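Transcript levels were measured on 6 whole-transcript arrays of wild-type Arabidopsis thaliana cotyledons. The cotyledons came from 6-day-old seedlings and were cultured in VISUAL, a tissue culture system in which leaf cells are induced to become vascular cells. The induction medium held the auxin 2,4-D, the cytokinin kinetin, and bikinin, an inhibitor of GSK3-like kinases that switches on brassinosteroid signalling. The sugar in the medium was either 5% glucose or 5% sucrose. Each sugar was sampled at 0, 24 and 48 h, which gave 6 groups of 1 array each, so no group had a replicate and the number of arrays limits the precision. Sampling times were taken from the sample titles. A separate time label differed from the title on 5 of the 6 arrays, giving 34 h for the glucose 24 h array and 72 h for the glucose 48 h array and for all 3 sucrose arrays.

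The 0 h arrays separated from the cultured ones. The first principal component held 71.8% of the variance and set both 0 h arrays (scores -147.8 and -138.5) apart from the 4 cultured arrays (59.3 to 94.1). Along the second component (18.4%), the cultured arrays ran from sucrose 24 h (72.0) through glucose 24 h (30.9) and sucrose 48 h (-3.30) to glucose 48 h (-97.4). Control probe sets of high GC content that match no plant sequence, a measure of background, had a median deposited log2 signal of 8.98 and 8.30 on the glucose and sucrose 0 h arrays. The same controls read 7.54 and 7.36 at 24 h and 8.01 and 7.23 at 48 h.

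**Figure D1:**
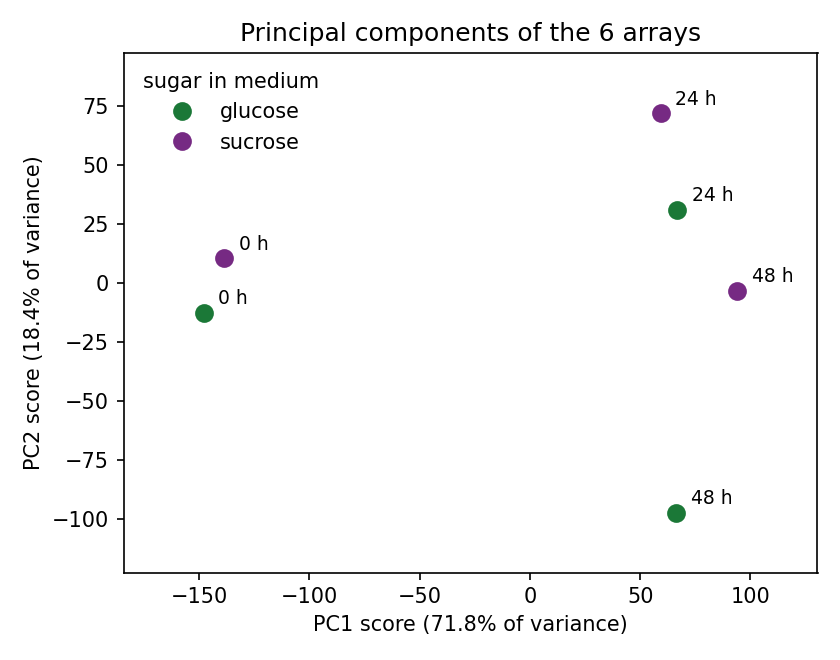
Scores of the 6 arrays on the first 2 principal components of the scaled log2 signals of the tested probe sets, coloured by sugar and labelled with the time after induction. The 0 h arrays lie at -147.8 and -138.5 on the first axis, and the glucose 48 h array lies lowest on the second, at -97.4.

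The first question was how the cotyledon transcriptome differed after 24 h of induction. Photosynthesis genes fell, stress genes responsive to abscisic acid (ABA) and osmotic change fell, and anthocyanin genes rose. All 9 tested photosynthesis genes were lower at 24 h than at 0 h, with a median log2 difference of -3.82, and all 6 ABA and osmotic response genes were lower, with a median of -3.54. All 4 anthocyanin genes were higher, by a median of 2.81. The ABA and anthocyanin medians are bounds, as members at the floor enter them. In the limma model over both sugars, 6248 probe sets were higher and 5120 lower at 24 h among 25826 tested, of which 1921 and 2389 matched 1 named gene.

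Among the photosynthesis genes, the photosystem I subunit PSAN (AT5G64040) fell by 5.35 ± 0.27 on the log2 scale (SE, 2 arrays against 2; adjusted p = 0.0018 in limma). Phosphoribulokinase, PRK (AT1G32060), an enzyme of the Calvin cycle, fell by 5.13 ± 0.28, the antenna protein LHCB4.2 (AT3G08940) by 4.41 ± 0.31 and the photosystem I subunit PSAE-1 (AT4G28750) by 4.12 ± 0.21. PSAN, PRK and LHCB4.2 were above the signal floor on the glucose array alone at 24 h. Each of the 9 genes passed both over all probe sets and adjusted over the list alone. The list stood apart from other probe sets by camera (adjusted p = 2.6e-07), and not with an estimated correlation (adjusted p = 0.610). The dehydrin COR47 (AT1G20440) fell by 4.87 ± 0.31, and the cold- and ABA-regulated genes COR15A (AT2G42540) and KIN2 (AT5G15970) by 4.00 ± 0.35 and 3.81 ± 0.24. COR15B (AT2G42530) lay at the floor on both 24 h arrays and was at least 9.70-fold lower. All 6 passed on both counts, the list's camera test gave an adjusted p of 0.00012, and the estimated correlation gave an adjusted p = 0.610.

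DFR (AT5G42800), dihydroflavonol reductase of the anthocyanin pathway, rose by 5.54 ± 0.56 (adjusted p = 0.0034). The anthocyanin glucosyltransferase gene AT4G14090, below the floor on the sucrose 0 h array, rose by 2.90 ± 0.36, UF3GT (AT5G54060), at the floor at 0 h, was at least 6.64-fold higher, and the malonyltransferase gene AT5MAT (AT3G29590) rose by 1.93 ± 0.32. The 4 genes passed over all probe sets and adjusted over the list alone, and the list test gave an adjusted p of 0.016 (adjusted p = 0.716 with an estimated correlation). Among auxin response genes, GH3.1 (AT2G14960) and GH3.3 (AT2G23170), which encode enzymes that conjugate auxin to amino acids, rose by 5.54 ± 0.23 and 6.27 ± 0.21. GH3.3 was above the floor on 1 of the 2 arrays at 0 h. IAA30 (AT3G62100) was at least 3.66-fold higher, and WES1 (AT4G27260), another GH3 gene, fell by 1.68 ± 0.41. In all, 3 of the 5 tested auxin genes rose and 1 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.149). The 3 cell cycle genes tested all rose, among them the Aurora kinase gene AUR1 (AT4G32830) by 3.16 ± 0.43 and the replication licensing gene PRL (AT4G02060) by 2.07 ± 0.52, while the list did not pass (adjusted p = 0.076).

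Outside the lists, the largest rises at 24 h included HAT2 (AT5G47370), a homeodomain-leucine zipper gene (5.39 ± 0.19), AT4G23680 (5.41 ± 0.35), AT4G03292 (5.00 ± 0.60), AT3G27400 (4.98 ± 0.38) and sks15 (AT4G37160), related to the multicopper oxidase-like gene SKU5 (4.52 ± 0.28). AT3G26470 (4.44 ± 0.37), AT1G61255 (4.26 ± 0.22) and AT1G54010 (4.18 ± 0.39) completed the 10 highest. The largest falls were those of ABR1 (AT5G64750), an ethylene response factor gene named as a repressor of ABA response (-6.64 ± 0.45), and NdhL (AT1G70760), a subunit of the chloroplast NADH dehydrogenase-like complex (-5.47 ± 0.34). They were followed by AT2G22880 (-5.39 ± 0.30), AT1G51090 (-5.33 ± 0.29), the chlorophyll synthesis gene PORB (AT4G27440; -5.31 ± 0.37) and FAMT (AT3G44860), a farnesoic acid methyltransferase gene (-5.11 ± 0.49). The glucosyltransferase genes UGT85A2 (AT1G22360) and UGT73B5 (AT2G15480) fell by 5.10 ± 0.50 and 4.91 ± 0.29, and AT3G07195 and AT5G56980 by 5.08 ± 0.28 and 4.99 ± 0.23.

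Few vascular genes carried a named probe set, and at 24 h 1 phloem gene fell while 1 phloem and 1 procambium gene rose. None of the 3 xylem vessel genes passed: GUT2 (AT1G27440), a glucuronoxylan synthesis gene, differed by 1.03 ± 0.48, IRX15-L (AT5G67210) by -0.98 ± 0.36, and IRX15 (AT3G50220) was at the floor on all 4 arrays compared. Of 4 phloem genes, OPS (AT3G09070), needed for protophloem formation, was at least 3.78-fold higher and the sucrose exporter gene SWEET11 (AT3G48740) fell by 3.18 ± 0.41, while CLE26 (AT1G69970), at the floor at 24 h, was at least 1.65-fold lower and did not pass, and CLE45 (AT1G69588) was at the floor. Of 5 procambium and cambium genes, the class III homeodomain-leucine zipper gene PHV (AT1G30490) rose by 1.03 ± 0.29 (adjusted p = 0.039). LHW (AT2G27230) differed by 0.93 ± 0.42, and the receptor kinase genes AT1G08590 and AT4G28650 by 0.43 ± 0.29 and 0.01 ± 0.28. MOL1 (AT5G51350), a further receptor kinase gene, was at the floor at 0 h and on the sucrose 24 h array, and none of these 4 passed. Adjusted over the list alone, 0 of 3 xylem, 2 of 4 phloem and 0 of 5 procambium genes passed. The camera tests of these lists, and of the starch, sucrose and hexose, and reference gene lists, gave adjusted p-values from 0.553 to 0.834. For starch the median (0.06) was positive while the mean (-0.17) and the test pointed lower, and for xylem the test pointed lower with a mean of 0.02.

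The 24 h counts rested on the pair of 24 h arrays: the number of calls was 0 without either of them, 6178 without the glucose 48 h array, 5870 without the sucrose 48 h array and 7296 without the glucose 0 h array. With the signals as deposited, an alternative chosen after seeing the data, 8019 probe sets were higher and 3881 lower, and the median log2 difference of all tested probe sets was 0.357 against 0.104 after scaling.

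The second question was how the transcriptome differed after 48 h of induction. Photosynthesis genes fell (9 of 9, median log2 difference -4.06), ABA and osmotic response genes fell (6 of 6, median -3.82), and cell cycle genes rose (3 of 3, median 4.86). Auxin response genes rose on balance, with 4 higher and 1 lower of 5 and a median of at least 2.29. That median is a bound, as it is the value of IAA30, at the floor at 0 h. The ABA median is a bound too, as COR15B, which enters it, lay at the floor at 48 h. GUT2, the glucuronoxylan synthesis gene, rose by 2.77 ± 0.48 (SE, 2 arrays against 2; adjusted p = 0.0099 in limma). The rise of GUT2 was 4.26 in glucose and 1.27 in sucrose, each between 2 single arrays. Over both sugars, 5715 probe sets were higher and 5137 lower at 48 h than at 0 h among the 25826 tested, of which 2278 and 2346 matched 1 named gene.

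COR15A fell by 7.29 ± 0.35 at 48 h, the largest fall among the named genes chosen by rule, and KIN2 by 5.61 ± 0.24. COR47 fell by 4.37 ± 0.31, and COR15B was again at least 9.70-fold lower. In the photosynthesis list, PSAN fell by 5.18 ± 0.27, PSAE-1 by 5.11 ± 0.21, PRK by 5.06 ± 0.28 and LHCB4.2 by 4.09 ± 0.31. PRK was above the floor on 1 of the 2 arrays at 48 h. Both lists passed by camera (adjusted p = 1.6e-07 for photosynthesis and 6.1e-05 for the ABA list), and neither with an estimated correlation (adjusted p = 0.576 for each). Every tested member of both lists also passed adjusted over the list alone.

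The Aurora kinase genes AUR1 and AUR2 (AT2G25880) were higher at 48 h, AUR1 by 4.86 ± 0.43 and AUR2, at the floor at 0 h, by at least 36.0-fold. PRL rose by 2.52 ± 0.52. The cell cycle list passed by camera (adjusted p = 0.034), but not with an estimated correlation (adjusted p = 0.733) or with fry (adjusted p = 0.055). Of its genes, 3 of 3 were past the threshold over all probe sets and adjusted over the list alone. Deposited signals without scaling ended the camera call of the cell cycle list (adjusted p = 0.065) and that of the auxin list (adjusted p = 0.099 against 0.047). With an estimated correlation the auxin list had an adjusted p = 0.654. GH3.3 rose by 5.71 ± 0.21 and GH3.1 by 4.38 ± 0.23, IAA30 was at least 4.90-fold higher, IAA29 (AT4G32280) at least 3.36-fold higher, and WES1 fell by 2.26 ± 0.41. The 5 auxin genes passed also when adjusted over the list alone. DFR, still higher by 3.39 ± 0.56 at 48 h, was the only one of the 4 anthocyanin genes past the threshold (adjusted p = 0.167 for the list). This mean hides a difference between the sugars: DFR was higher by 1.51 in glucose and 5.26 in sucrose. Between 2 single arrays each, the list median was -0.06 in glucose (2 higher, 2 lower) and 2.00 in sucrose (4 of 4 higher). Members at the floor enter both medians.

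In the vascular lists, 1 of 3 xylem, 3 of 4 phloem and 2 of 5 procambium genes passed at 48 h, in the same numbers adjusted over the list alone. CLE45, a phloem peptide gene at the floor at 0 h, was at least 4.60-fold higher, OPS at least 5.08-fold higher, and SWEET11, at the floor on both 48 h arrays, was at least 61.9-fold lower. PHV rose by 1.48 ± 0.29 and MOL1, at the floor at 0 h, was at least 1.61-fold higher. IRX15, at the floor at 0 h, was at least 2.09-fold higher and did not pass. IRX15-L (0.23 ± 0.36), CLE26 (-0.22 ± 0.29), LHW (1.17 ± 0.42), AT1G08590 (0.73 ± 0.29) and AT4G28650 (0.01 ± 0.28) did not pass. None of the 3 lists passed as a whole (adjusted p = 0.310 for xylem, 0.952 for phloem and 0.167 for procambium). These values average sugars that differed. Between 2 single arrays each, the xylem median was at least 1.96 in glucose (3 of 3 higher) and at least 0.17 in sucrose (2 higher, 1 lower). IRX15-L differed by 1.26 in glucose and -0.81 in sucrose. CLE26 differed by 0.46 in glucose and by -0.89 or less in sucrose, where it lay at the floor. For phloem, the median (0.99) and mean (-0.41) differed in sign.

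Among the 10 highest named genes at 48 h were AT3G27400 (6.13 ± 0.38), the RING finger gene ATL4H (AT4G17905; 5.80 ± 0.32), AT4G20320 (5.75 ± 0.39), AT4G23680 (5.68 ± 0.35), sks15 (5.30 ± 0.28) and the beta-glucosidase gene BGLU15 (AT2G44450; 5.27 ± 0.34). AT1G28400 (5.25 ± 0.32), AT3G54040 (5.19 ± 0.25), AT2G28620 (5.17 ± 0.54) and HAT2 (5.13 ± 0.19) made up the rest. After COR15A, the lowest were ABR1 (-6.31 ± 0.45), AT5G42530 (-6.17 ± 0.38), AT1G67865 (-5.95 ± 0.23), AT2G38240 (-5.93 ± 0.57), AT1G61890 (-5.79 ± 0.23) and AT1G67870 (-5.75 ± 0.19). KIN2, the zinc finger gene STZ (AT1G27730; -5.57 ± 0.20) and AT1G35350 (-5.23 ± 0.35) completed them. Among lists with fewer than 3 tested genes, the cytokinin response regulator gene ARR15 (AT1G74890) was at least 3.66-fold higher at 24 h and at least 2.19-fold higher at 48 h. RR16 (AT2G40670), the other cytokinin gene, was at the floor at 24 h, at least 2.73-fold lower, and differed by 0.02 ± 0.70 at 48 h, and passed at neither time. In glucose RR16 differed by 1.73 at 48 h. In sucrose it lay at the floor at 48 h and differed by -1.69 or less. In the guard cell list, FMA (AT3G24140) fell by 1.15 ± 0.31 at 48 h and SPCH (AT5G53210) was at least 1.84-fold lower at both times. The sugar starvation genes MCCB (AT4G34030) and AT3G15450 passed at neither time. The brassinosteroid synthesis, defence and epidermis lists had no tested member.

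In the starch list, PWD (AT5G26570) and DPE1 (AT5G64860) fell at both times, by 1.26 ± 0.29 and 1.64 ± 0.38 at 24 h. The ADP-glucose pyrophosphorylase gene APL3 (AT4G39210) rose by 1.57 ± 0.27 at 24 h, and the amylase gene AMY1 (AT4G25000) rose by 2.35 ± 0.53 at 48 h. Adjusted over the list alone, 3 of 6 starch genes passed at 24 h and 4 at 48 h, and the list did not pass at 48 h (adjusted p = 0.523). Of 4 sucrose and hexose genes, the vacuolar sugar transporter gene TMT2 (AT4G35300) rose at both times (1.60 ± 0.37 and 1.40 ± 0.37) and TMT1 (AT1G20840) at 24 h (0.72 ± 0.20). Among 4 reference genes often used for normalization, AT4G34270 rose by 0.82 ± 0.19 at 24 h and 1.11 ± 0.19 at 48 h, while AT2G28390, PEX4 (AT5G25760) and AT4G26410 did not pass at either time. As at 24 h, the 48 h count rested on its own pair of arrays: it was 0 without either 48 h array, 6468 without the glucose 24 h array and 6348 without the sucrose 24 h array. As deposited, 6718 probe sets were higher and 4361 lower at 48 h, with a median log2 difference of 0.284 against 0.127.

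**Figure D2:**
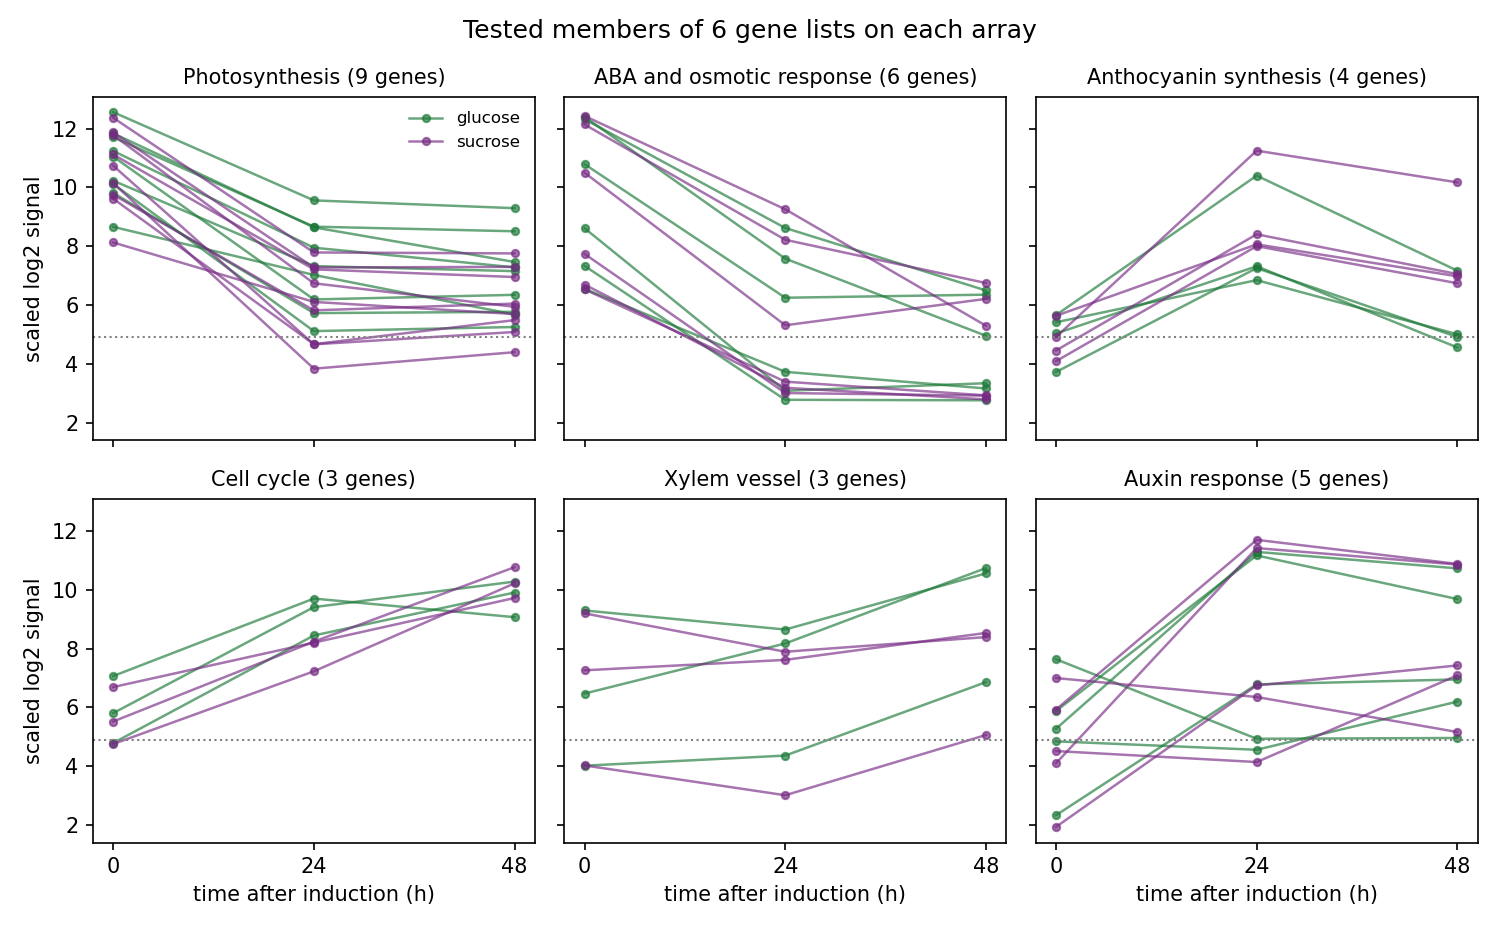
Scaled log2 signal (vertical axis) against time after induction in hours (horizontal axis) for the tested members of 6 gene lists, with 1 line per gene and sugar and 1 array per point. The dotted line marks the signal floor of 4.90. All 9 photosynthesis and all 6 ABA and osmotic response genes lie lower at 24 and 48 h than at 0 h, and the 3 xylem vessel genes lie higher in glucose than in sucrose at 48 h.

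The change between 24 and 48 h was smaller. No probe set passed the limma threshold over both sugars (0 of 25826, smallest adjusted p = 0.082), although 4872 had an unadjusted p under 0.05. As lists, xylem vessel genes (mean log2 difference 1.34, adjusted p = 0.024) and cell cycle genes (median 1.70, adjusted p = 0.025) were higher at 48 h than at 24 h, and anthocyanin genes were lower (median -1.85, adjusted p = 0.0027). With an estimated correlation each of these 3 lists had an adjusted p = 0.772. None of them passed with fry (adjusted p = 0.410 for xylem, 0.418 for cell cycle and 0.410 for anthocyanin). Adjusted over the list alone, 2 of 3 xylem, 2 of 3 cell cycle and 4 of 4 anthocyanin genes passed. The other 8 lists had adjusted p-values from 0.214 to 0.898, with a median of -0.03 and a mean of 0.01 for starch.

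Of the genes named by the size of their difference, none past the threshold, AT5G41470 (4.19 ± 0.57), AT3G18670 (3.62 ± 0.30), AT2G27140 (3.53 ± 0.31), the defensin gene PDF2.1 (AT2G02120; 3.33 ± 0.28) and AT1G63300 (3.17 ± 0.29) had higher values at 48 h. AT5G42530 (-4.00 ± 0.38), COR15A (-3.29 ± 0.35), AT5G08760 (-3.06 ± 0.24), AT1G72920 (-2.78 ± 0.40) and AT3G54400 (-2.46 ± 0.30) had lower ones. The count of calls was 328 without the glucose 0 h array, 387 without the sucrose 0 h array, 445 over the probe sets above the floor on all 6 arrays, and 169 with no floor or filter.

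The third question, in the series title, was the effect of the sugar. At 24 and 48 h, photosynthesis genes as a list were lower in sucrose than in glucose (median log2 difference -1.28), xylem vessel genes were lower (-1.38) and anthocyanin genes were higher (1.61). No single probe set passed the threshold for a sugar difference common to 24 and 48 h (0 of 25826 in limma, smallest adjusted p = 0.151), although 2613 had an unadjusted p under 0.05. The camera tests gave adjusted p-values of 1.2e-08 for photosynthesis, 0.00020 for anthocyanin and 0.0041 for xylem. Each of these 3 lists had an adjusted p = 0.523 with an estimated correlation. With fry none of them passed (adjusted p = 0.153 for photosynthesis, 0.294 for anthocyanin and 0.439 for xylem). The other 8 lists had adjusted p-values from 0.062 to 0.933, the lowest that of auxin response (median 0.45). The tests of the procambium and ABA lists pointed lower while their means were 0.02 and 0.07.

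Adjusted over the list alone, 5 of 9 photosynthesis genes were lower in sucrose. PSAE-1 differed by -1.71 ± 0.21, the photosystem II subunit PSBW (AT2G30570) by -1.65 ± 0.18, the antenna protein LHCB4.1 (AT5G01530) by -1.30 ± 0.29, Rubisco activase, RCA (AT2G39730), by -1.30 ± 0.19 and PSAN by -1.28 ± 0.27. The list's median difference between the sugars was -0.19 at 0 h, -1.29 at 24 h and -1.10 at 48 h, at percentiles 6.60, 0 and 0.01 of 10000 random lists matched for signal. All 4 anthocyanin genes were higher in sucrose adjusted over the list alone: DFR by 1.93 ± 0.56, AT4G14090 by 1.62 ± 0.36, AT5MAT by 1.59 ± 0.32 and UF3GT by 1.29 ± 0.35. Their median difference was -0.07 at 0 h, 0.97 at 24 h and 2.06 at 48 h. Of the 3 xylem genes, IRX15-L passed adjusted over the list alone (-1.46 ± 0.36), while GUT2 (-1.38 ± 0.48) did not, nor did IRX15, which was at the floor in both sugars at 24 h and differed by -1.80 at 48 h. The xylem median was 0 at 0 h, -0.56 at 24 h and -2.16 at 48 h. Beside these lists, the high-GC background controls, on the scaled signals, were lower in sucrose by a median log2 difference of -0.72 at 0 h, -0.15 at 24 h and -0.94 at 48 h.

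The genes with the largest sugar difference of the same sign at both times, none past the threshold, included 2 expansin genes, which loosen cell walls. EXPA8 (AT2G40610) was 5.06-fold lower in sucrose (log2 difference -2.34 ± 0.27; adjusted p = 0.203) and EXPB1 (AT2G20750) 5.32-fold lower (-2.41 ± 0.33). TBL33 (AT2G40320), a TRICHOME BIREFRINGENCE-LIKE gene of a family that acetylates cell wall xylan, differed by -2.36 ± 0.27, AT5G26330 by -2.53 ± 0.29 and AT3G16070 by -2.07 ± 0.28. In the other direction, AT1G51840 (2.90 ± 0.49), AT3G57460 (2.78 ± 0.34), AT1G76470 (2.14 ± 0.44), AT1G72240 (2.03 ± 0.34) and AT2G14900 (2.02 ± 0.26) had higher values in sucrose. OPS (0.07 ± 0.44), PHV (0.38 ± 0.29), LHW (0.10 ± 0.42), AT4G28650 (-0.23 ± 0.28), AT1G08590 (-0.10 ± 0.29) and MOL1 (-0.07 ± 0.17) did not pass. Nor did SWEET11, at the floor in both sugars at 48 h, or CLE45, at the floor in both at 24 h. CLE26, at the floor on every cultured array except glucose 48 h, did not pass either, and its log2 signal at 48 h was lower in sucrose by at least 1.02. Over the probe sets above the floor on all 6 arrays, 19 passed for the sugar difference, and 4 passed without the glucose 0 h array, without the sucrose 0 h array or with no floor or filter.

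The sugars were also compared at each time. Between single arrays, 1635 of 24993 probe sets were at least 2-fold apart in the 0 h pair, 1699 of 24074 at 24 h and 3624 of 24353 at 48 h. Those higher and lower in sucrose numbered 1220 and 415 at 0 h, 837 and 862 at 24 h, and 2083 and 1541 at 48 h. Among probe sets with 1 named gene the counts were 402, 723 and 1094, and at 48 h the balance was the opposite, with 299 higher and 795 lower in sucrose. These counts compare 2 arrays and have no replicate check. Without a block of unlisted probe sets whose signal differed between arrays, an omission chosen after seeing the data, 884 were 2-fold apart at 0 h and 2294 at 48 h. The balance at 48 h turned to 896 higher and 1398 lower without that block, 1031 and 1196 with the floor at the 55th percentile, and 1590 and 1701 with quantile normalization, and was 3025 and 1229 as deposited. At 0 h it was 1109 and 626 with quantile normalization and 1000 and 603 with median centring. Probe by probe, limma passed no sugar difference at 24 h, at 48 h or between the 2 times when its spread came from the 0 h pair (0 of 25826 each). Unadjusted p-values under 0.05 numbered 2955, 4472 and 3473 in that order. With the floor at the 55th percentile, 1606, 2313 and 2158 probe sets passed. In that model a probe set at the floor on both 0 h arrays has a residual of 0, so these counts do not rest on a measured spread alone. Over probe sets above the floor on all 6 arrays, 2, 103 and 1 passed.

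The sugar difference at 24 h and that at 48 h, which share no array, correlated at r = 0.296 across 25826 probe sets, which are not independent replicates. At least 2-fold at both times, 212 probe sets were higher and 207 lower in sucrose (65.9 and 48.9 for independent lists), and 43 went opposite ways. The difference of the 0 h pair, taken as having no sugar effect, correlated at r = 0.187 with that at 24 h and 0.219 with that at 48 h. With the 48 h pair it shared 373 higher and 33 lower (96.3 and 21.5 for independent lists), and 40 went opposite ways. With the 24 h pair these were 94, 27 (37.9 and 12.6) and 25. Agreement between pairs was thus not limited to the cultured arrays. The change from 0 to 24 h was shared more widely: in glucose and in sucrose it correlated at r = 0.884, and from 0 to 48 h at r = 0.861. The change from 24 to 48 h correlated at r = 0.542 between the sugars, with 4984 probe sets at least 2-fold apart in glucose and 2529 in sucrose. Between those 2 arrays in glucose, AMY1, GUT2 and IRX15-L differed by 3.22, 2.56 and 1.91, and in sucrose by 1.17, 0.92 and 0.50. The 3 cell cycle genes AUR1, AUR2 and PRL went the other way, with 0.87, 1.46 and -0.63 in glucose and 2.53, 2.996 and 1.52 in sucrose.

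**Figure D3:**
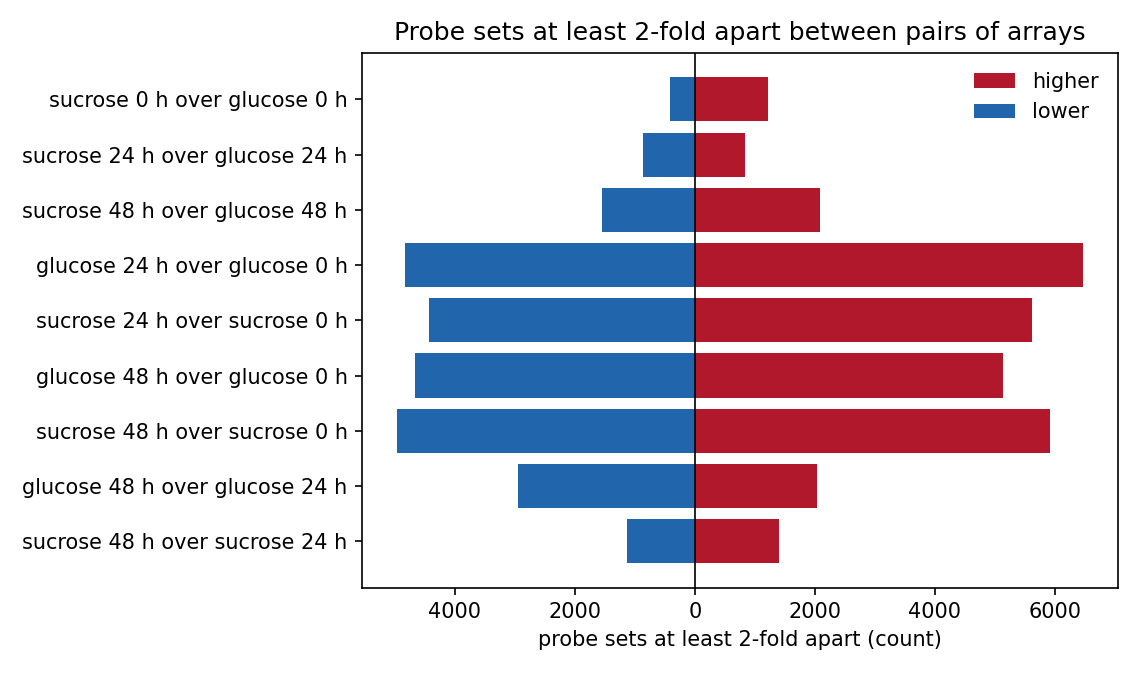
Number of probe sets at least 2-fold higher (right) or lower (left) between pairs of single arrays, out of those above the signal floor on at least 1 array of the pair. The 3 sucrose over glucose pairs give 1635, 1699 and 3624 probe sets at 0, 24 and 48 h, and the pairs against 0 h give 9796 to 11301.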

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

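The list tests of the change of the sugar difference, and the tests of an earlier point, of the glucose 48 h array, of the 0 h pair and of the background beside the photosynthesis and anthocyanin lists, were chosen only after the results were seen. By a camera test of the change, the sucrose minus glucose difference changed between 24 and 48 h in 4 gene lists. The change was taken between 4 single arrays, with 1 residual degree of freedom from the 0 h pair. The xylem vessel list shifted by a median log2 of -1.64 (3 of 3 genes lower; camera adjusted p = 0.014), and the cell cycle list by 1.66 (3 of 3 higher; adjusted p = 0.022). The anthocyanin list shifted by 1.07 (4 of 4 higher; adjusted p = 0.022) and the starch list by -0.75 (5 of 6 lower; adjusted p = 0.022). With an estimated correlation each of the 4 had an adjusted p = 0.646. With fry, cell cycle, anthocyanin and starch did not pass (adjusted p = 0.166, 0.142 and 0.531).

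The first pattern was the wide difference between the 0 h and the cultured arrays. Background controls were brightest at 0 h, so array background was tested as its source. Of the 2583 brightest tested probe sets, 1675 passed the threshold at 48 h, a share of 0.648 (95% interval 0.630 to 0.667). That argues against a background confined to dim probe sets as the whole cause. The interval takes probe sets as independent and holds no spread between arrays. The high-GC controls themselves read 9.17 (glucose) and 8.44 (sucrose) at 0 h on the scaled signals. The test therefore cannot exclude background in bright probe sets. The bioB spike-in controls also differed with time. Their mean deposited log2 signal was 10.07 (glucose) and 9.87 (sucrose) at 0 h, and 8.72 to 9.17 on the cultured arrays. For the brighter cre spike-in controls it was 12.95 to 13.09 on all 6 arrays. A technical difference between 0 h and cultured arrays that varies with signal thus stays open. Time in culture, hormones and bikinin stay open, since the design confounds them, and the response to induction is a hypothesis here, not a separate finding.

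The second pattern was the larger sugar difference at 48 h than at 0 h. Among the brightest probe sets (6456 compared at 48 h and 6455 at 0 h), 552 were 2-fold apart at 48 h and 150 at 0 h. The ratio of 3.68 (95% interval 3.07 to 4.41) argues against a background of the glucose 48 h array confined to dim probe sets. Its interval, too, takes probe sets as independent and holds no spread between arrays. The high-GC controls read 8.06 (glucose) and 7.12 (sucrose) at 48 h on the scaled signals, so background in bright probe sets stays open. Across probe sets, the common sugar term and the change from 24 to 48 h correlated at r = -0.641. Both are built from the same 4 arrays, and extra noise on the glucose 48 h or sucrose 24 h array would give a negative value too, so an earlier point of that change in sucrose cannot be told apart from such noise. Without the glucose 48 h array the correlation was -0.289, which argues against that array standing apart alone, although a deviating sucrose 24 h array could also give this value, and 1 array per group keeps a difference between cultures open.

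The third pattern was the lower signal of photosynthesis genes and the higher signal of anthocyanin genes in sucrose. The larger ratio of the 0 h to the 24 h list median, that of photosynthesis, was 0.144. It argues against a difference already there at 0 h in the photosynthesis genes. For anthocyanin, AT4G14090 was below the floor on the sucrose 0 h array and UF3GT on both 0 h arrays. The floor thus partly set that list's 0 h median, and the ratio cannot decide for it. The background controls differed between the sugars by 0.120 of the photosynthesis median at 24 h, which argues against array background at that time. At 48 h they differed by 0.851 of it in the same direction, but the photosynthesis median lay at percentile 0.02 of 10000 random lists matched on signal at 48 h, which argues against a background shared by probe sets of like signal. For anthocyanin genes at 48 h that ratio was -0.456, as background was lower in sucrose and the genes were higher, which argues against background there. A sugar effect on these genes stays a hypothesis, found and tested on the same 6 arrays, and a difference between single cultures and a background that varies with probe GC content were not tested and stay open.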

How the results depend on the processing

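Signals as deposited, the omission of the odd-numbered block and the lists for the change of the sugar difference were chosen after seeing the data; the other settings were fixed beforehand. A sugar term over all 3 times, which pairs the time differences within each sugar, gave 11741 calls at 24 h and 11289 at 48 h. Where a value moved, the cause was not tested, except that leaving out an array leaves fewer samples and a lone array is then assumed to vary like the others. Low signals lie near background, so results there depend on the floor. The counts at 24 and 48 h against 0 h stayed within 1.5 times under every setting that kept all 6 arrays (8775 to 12084 and 8861 to 11419). Leaving out 1 array gave 0 to 9079 calls at 24 h, 0 to 8394 at 48 h, 0 to 387 for 48 against 24 h and 0 to 4 for the common sugar term. With no floor or filter, 169 probe sets passed for 48 against 24 h and 4 for the common sugar term; above the floor on all 6 arrays, 445 and 19 passed, and 2, 103 and 1 for the sugar at 24 h, at 48 h and its change. With the 55th percentile as floor those 3 counts were 1606, 2313 and 2158. Their model takes its spread from the 0 h pair, and the floor sets it to 0 for probe sets at the floor on both arrays. Probe sets 2-fold apart in the 0 h sugar pair numbered 2762 with the 25th percentile, 838 with the 55th, 4191 with no floor and 884 without the block. At 48 h they numbered 2227 with the 55th percentile, 6213 with no floor and 2294 without the block, and at 24 h 3172 with no floor. With no floor, 16989 differed between 24 and 0 h in glucose, and 7537 and 4132 between 48 and 24 h in glucose and sucrose.

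Among the lists, an estimated correlation ended every call: adjusted p = 0.610 for photosynthesis and ABA response and 0.716 for anthocyanin at 24 h; 0.576 for photosynthesis and ABA response, 0.733 for cell cycle and 0.654 for auxin response at 48 h; 0.772 for xylem, cell cycle and anthocyanin between 24 and 48 h; 0.523 for xylem, photosynthesis and anthocyanin by sugar; and 0.646 for the 4 lists whose sugar difference changed. With fry, auxin response passed at 24 h (0.0099), and cell cycle did not at 48 h (0.055). Nor did xylem, cell cycle and anthocyanin between 24 and 48 h (0.410, 0.418 and 0.410), xylem, photosynthesis and anthocyanin by sugar (0.439, 0.153 and 0.294), or cell cycle, anthocyanin and starch for the change of the sugar difference (0.166, 0.142 and 0.531). With no floor, cell cycle passed at 24 h (0.013) and anthocyanin at 48 h (0.047). As deposited, cell cycle (0.065) and auxin response (0.099) did not pass at 48 h, nor cell cycle (0.060) and anthocyanin (0.059) for the change of the sugar difference. Other list results kept their side of the threshold.

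Of the named genes, 19 values turned in sign, none of them past the threshold. AT4G28650 read -0.21 with quantile normalization and -0.084 with median centring at 24 h, and -0.14 and -0.045 at 48 h. With 1 array left out it ranged from -0.027 (without the glucose 0 h array) to 0.045 at 24 h and from -0.025 (the same array) to 0.047 at 48 h. MOL1 ranged from -0.072 (without the glucose 24 h array) to 0.36 at 24 h, IRX15-L from -0.48 (without the glucose 48 h array) to 0.93 at 48 h, and CLE26 from -0.70 to 0.29 (without the sucrose 48 h array) at 48 h. For the common sugar term, OPS read -0.0073 with quantile normalization and MOL1 0.091 without the block. With 1 array left out, OPS ranged from -0.74 (without either 48 h array) to 0.88, LHW from -0.047 (without either 48 h array) to 0.26, AT1G08590 from -0.23 to 0.040 (without either 24 h array) and MOL1 from -0.28 to 0.14 (without either 24 h array). Over 169 genes and comparisons, 2389 values kept their side of the threshold, 51 newly passed and 311 no longer passed, 280 of these with 1 cultured array left out; of the values from the arrays of 1 sugar alone, 120 lay within 1 SE of the joint value and 134 further from it.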

Other observations

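The tests of gene families by symbol were chosen only after the data were seen. UDP-glycosyltransferase genes with symbols that open with UGT were lower in culture as a family. Of 32 tested, 15 fell and 2 rose at 24 h (median log2 difference -0.83, camera adjusted p = 0.0079 over 21 families), and 13 fell and 1 rose at 48 h (median -0.73, adjusted p = 0.00050). With an estimated correlation, the adjusted p was 0.800 at 24 h and 0.790 at 48 h. UGT76E12 (AT3G46660) fell by 3.47 ± 0.25 at 24 h and UGT76E11 (AT3G46670) by 2.38 ± 0.35 at 24 h and 4.05 ± 0.35 at 48 h (SE, 2 arrays against 2). UGT76E12, at the floor on both 48 h arrays, was at least 52.7-fold lower there. UGT73D1 (AT3G53150), below the floor on the glucose 0 h array, rose at both times, by 0.87 ± 0.23 and 1.14 ± 0.23. UGT76B1 (AT3G11340), at the floor at 0 h, was higher at 24 h (adjusted p = 0.034). The glycosyltransferase genes AT4G14090 (2.90 ± 0.36) and UF3GT (at least 6.64-fold) also rose at 24 h, and the symbol rule left them out of the family. The family's direction was the same with quantile normalization (median -0.94 and -0.80), median centring (-0.88 and -0.77) and signals as deposited (-0.61 and -0.59).

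By sugar, genes with symbols opening with BGLU, TBL and ATG were lower in sucrose as families, with median log2 differences of -0.39, -0.24 and -0.64 (adjusted p = 0.045, 0.047 and 0.048). No single member passed, and each of these families had an adjusted p = 0.795 with an estimated correlation. Quantile normalization kept the direction and ended these 3 calls (adjusted p = 0.059 each). Median centring ended that of ATG (0.051), no floor that of BGLU (0.094), and omission of the odd-numbered block those of ATG and TBL (0.110 each).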
